A study of Homo sapiens with 2 samples.

How the data were processed

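RNA was measured in nuclei of 2 cultures of sensory neurons made from WTC11, an established human induced pluripotent stem cell line. Per the labels' protocols, the cells passed through a neural crest stage, were plated at 50000 cells per square centimetre and were kept for 21 days in a neural induction medium. In the group NC-iSN1 doxycycline was given from day 0 to day 14 and neurotrophic factors from day 8. In the group NC-iSN2 doxycycline was given for 24 hours from day 0, and neurotrophic factors together with retinoic acid from day 0. The gene that doxycycline controlled is not given in the sources used here. Doxycycline timing, neurotrophic factor timing and retinoic acid differ together between the groups, so no difference can be assigned to any of them. Nuclei were isolated with EZ prep lysis buffer, and libraries were made on the droplet-based 10x Chromium system. Each group holds 1 library.

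The deposited tables hold raw UMI counts per gene and nucleus barcode, for the same 27304 gene symbols in both libraries. Per the submitters' processing notes, bcl2fastq 2.17, Cell Ranger 2.1.0, STAR 2.5.3a and Seurat 3 were used with genome build GRCh38. The lowest number of detected genes in a nucleus was 998 in both tables, so barcodes with fewer genes are not in the tables and were not analysed here. The counts sum to 44403202 UMIs over 22804 nuclei of NC-iSN1 and to 33443444 UMIs over 15004 nuclei of NC-iSN2. Some symbols of the fixed lists, among them SOX2, HES5, NEUROG1 and NEUROD1, are not among the symbols of the tables and were not analysed here.

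Nuclei were to be kept with at least 200 detected genes and at most 10% mitochondrial UMIs, and without a doublet mark from Scrublet at an expected rate of 0.06. These filters removed 0 nuclei. Scrublet marked 0 nuclei in each library, so it is treated as not having worked, and doublets were not removed. An alternative chosen after seeing the data leaves out the 6% of nuclei with the highest UMI totals. Each library was clustered by itself on log-normalised counts with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, Python 3.11.15, fixed seed 1). Clusters were named from markers fixed before the data were examined. The thresholds were set after seeing the data. A cluster was called mesenchymal-like or glial-like with at least 3 markers of that class at 10 CPM or more and at 2-fold or more over the remaining nuclei, with 5 CPM added to both. It was called neuron-like with at least 3 neuronal markers at 1.2-fold or more above the non-neuronal clusters and fewer than 3 below them by the same factor. Other clusters stayed unnamed. So did a cluster that met the neuron-like rule but had more markers of another class than of neurons among its 10 leading genes. That last rule, also set after seeing the data, was not applied to mesenchymal-like or glial-like clusters and did not count cycling genes as a class. The NC-iSN2 cluster it left unnamed had PMEL among its leading genes. That cluster of 1202 nuclei had 10 neuronal markers above the non-neuronal clusters and 0 below. With both libraries clustered together, 852 of these nuclei fell in a cluster named neuron-like and 248 in another such cluster, counts added after seeing the data.

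Counts were summed per library over all nuclei and over neuron-like nuclei and scaled to the sum of the library (CPM, 1e6 times the share of UMIs). With 1 library per group there is no replicate check, no test and no p-value. Ratios of CPM carry an exact 95% interval (conditional binomial) and shares of nuclei an exact binomial 95% interval (Clopper-Pearson). Both cover counting error only. Genes with 0 UMIs enter a ratio at 3 counts, which is 0.0676 CPM over all nuclei of NC-iSN1 and 0.0897 CPM over those of NC-iSN2. A gene was described as higher in a library with at least 20 CPM there and a ratio of at least 2. These numbers of genes describe the 2 libraries and are not counts of genes changed by the treatment. The functions were tested on simulated data. All 100 genes altered 3-fold and all 100 altered 6-fold were recovered in each of the 2 comparisons, and 0 of 8165 and 0 of 8072 unaltered genes were called over all nuclei and in neuron-like nuclei. Both simulated libraries came from 1 mean profile with counting error only, and altered genes had at least 50 CPM. The simulation checks the calculation and gives no rate of false calls between cultures or preparations.

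Named genes follow a rule fixed beforehand. It takes the 12 largest ratios in each direction among protein-coding-like symbols with at least 50 CPM in the higher library, a preset group of sensory genes, and up to 4 members of each gene list with at least 20 CPM. The rule reads symbols, so the non-coding RNA HOTAIRM1 passed it. Of the 34 fixed lists, 30 had at least 5 members with at least 10 UMIs. The lists of HOX genes of groups 5 to 8 and 9 to 13, autonomic neurons and skeletal muscle had fewer in neuron-like nuclei and give no result there. Their median log2 ratio of CPM plus 1 was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to lie outside the random lists below percentile 2.5 or above percentile 97.5. Shares of nuclei were compared after thinning each nucleus to 1000 UMIs, which 0 nuclei of either library failed to reach. Thinning to 2000 UMIs left out 15556 nuclei of NC-iSN1 and 6876 of NC-iSN2. Positions and gene lengths come from GENCODE release 29 on GRCh38. Of 9225 genes with at least 20 CPM in either library, 91.2% had a length.

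Alternatives fixed beforehand changed the filter on nuclei, the scaling, the minimum level, the clustering, the added CPM and the thinning. Alternatives added after seeing the data left out nuclei whose barcode occurs in both tables, left out a cluster, changed the naming threshold or matched random lists on gene length as well. Length-matched lists used 10 expression bins, each split into 10 length bins. They drew only on genes with a length, which were 73.9% of the genes open to the lists. Genes on the Y chromosome and XIST were left out of the gene tables. Results for some further genes are not reported here.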

Results

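Single-nucleus RNA profiles were compared between 2 protocols that turn human neural crest cells, derived from the induced pluripotent stem cell line WTC11, into peripheral sensory neurons. The study's title frames the question as how subtypes of mechanosensory neurons can be programmed. NC-iSN1 received doxycycline from day 0 to day 14 and neurotrophic factors from day 8. NC-iSN2 received doxycycline for 24 hours, with neurotrophic factors and retinoic acid from day 0. Both were taken at 21 days. Each group is 1 library with no replicate, so every difference below is between these 2 libraries. NC-iSN1 held 22804 nuclei with a median of 1724 UMIs and NC-iSN2 held 15004 nuclei with a median of 2053 UMIs. Values are raw UMI counts from the authors, summed and scaled to the library (CPM). Brackets after ratios and shares give exact 95% intervals for counting error only.

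Neuron-like clusters made up most nuclei of both cultures. They held 73.3% of NC-iSN1 nuclei (72.7 to 73.9) and 74.3% of NC-iSN2 nuclei (73.6 to 75.0). Mesenchymal-like clusters, of which 1 per library was led by cycling genes such as TOP2A, held 12.6% and 14.9%. Glial-like clusters with SOX10, CDH19 and ERBB3 held 4.46% and 2.80%. Unnamed clusters held 9.60% and 8.01%. The unnamed NC-iSN2 nuclei met the rule on neuronal markers and were left unnamed only by the rule on leading genes. Several neuronal marker genes differed in level between the libraries, so no order is read from the neuron-like shares. Nuclei with at least 2 proliferation genes were few, at 1.99% (1.81 to 2.18) in NC-iSN1 and 1.65% (1.45 to 1.87) in NC-iSN2 after thinning to 1000 UMIs. Without thinning these were 4.75% and 3.79%. After thinning to 1000 UMIs, the share within neuron-like nuclei was 0.598% in NC-iSN1 and 0.323% in NC-iSN2, against 11.7% and 12.1% in glial-like nuclei.

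Messages for the touch channel PIEZO2 and the receptor RET were higher in NC-iSN2, and those for the cold receptor TRPM8 and the peptide CALCB were higher in NC-iSN1. In neuron-like nuclei PIEZO2, the mechanically gated channel of touch and proprioception, stood at 679 CPM in NC-iSN2 and 156 CPM in NC-iSN1, a ratio of 4.36 (4.22 to 4.50). RET, the receptor for the GDNF family, was 6.10-fold higher there (5.66 to 6.58). NTRK2 and NTRK3 stayed under a ratio of 2, at 1.94 (1.87 to 2.02) and 1.58 (1.47 to 1.71). TRPM8, the cold-activated channel, was 13.1-fold higher in NC-iSN1 (11.1 to 15.5), at 80.6 against 6.16 CPM. CALCB, which encodes a calcitonin gene-related peptide, was 23.7-fold higher in NC-iSN1 (21.0 to 26.8). Part of the NC-iSN2 level of NC-iSN1 genes came from nuclei whose barcodes occur in both tables. Without such nuclei, an alternative chosen after seeing the data, the TRPM8 ratio was 21.7 and the CALCB ratio 45.8. PIEZO2 lies on chromosome 18 from 10666483 to 11148762 and TRPM8 on chromosome 2 from 233917398 to 234019522 (GRCh38).

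**Figure D1:**
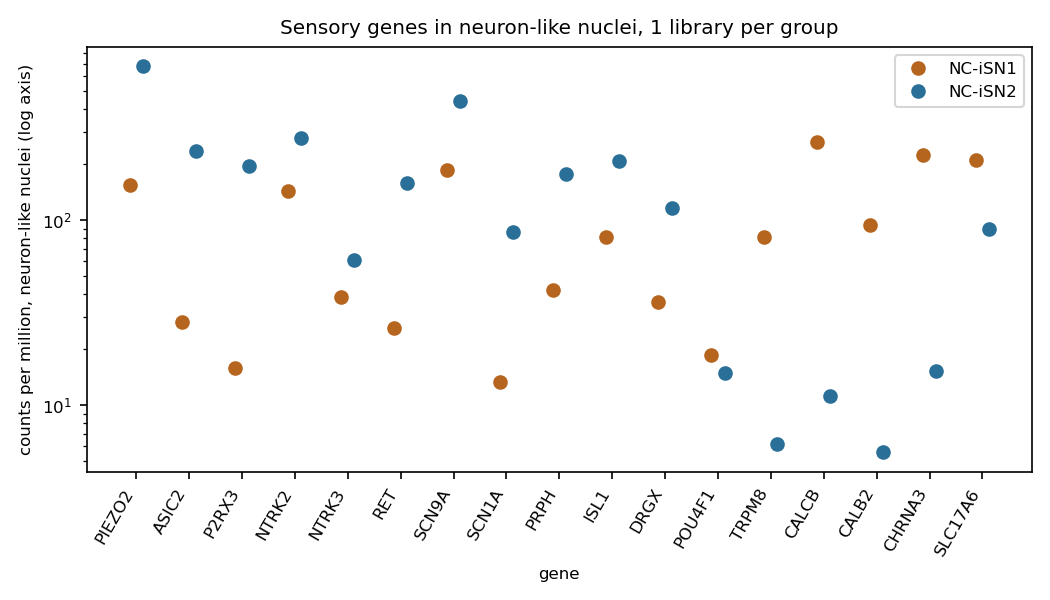
CPM (log axis) of 17 sensory genes in neuron-like nuclei, with 1 point per library and no error bars. PIEZO2 is at 156 CPM in NC-iSN1 and 679 CPM in NC-iSN2, and TRPM8 is at 80.6 and 6.16 CPM.

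Within neuron-like nuclei 1934 genes were at least 2-fold higher in NC-iSN1 and 1089 in NC-iSN2, of 9090 genes with at least 20 CPM in either library. Over all nuclei these were 1907 and 1108 of 9225 genes. The balance moved with the scaling. Median of ratios gave 2224 and 915 genes in neuron-like nuclei and 2315 and 847 over all nuclei, and totals without the 50 highest genes gave 1922 and 1370, and 1894 and 1392. Scaling by the median of ratios shifts all log2 ratios by 0.11 in neuron-like nuclei and 0.17 over all nuclei toward NC-iSN1. In neuron-like nuclei the ratios also went with gene length. Among genes of known length with at least 20 CPM, those shorter than 19919.5 bp had a median log2 ratio of 1.01 toward NC-iSN1. That median is itself beyond the 2-fold limit. Genes longer than 122044 bp had a median of -0.39, toward NC-iSN2. The numbers of genes and the ratios of named genes are not corrected for gene length. Among the largest ratios toward NC-iSN1 in neuron-like nuclei, for genes with at least 50 CPM, were EPGN (31.3-fold), the synaptotagmin SYT10 (23.7-fold), NUP62CL (22.9-fold), the kisspeptin receptor KISS1R (22.2-fold), RGS16 (20.1-fold), SIX3 (19.8-fold) and the calcium-binding protein CALB2 (17.0-fold). All of these ratios moved by more than 1.5 times without nuclei whose barcodes occur in both tables, where EPGN was at 146-fold, NUP62CL at 56.0-fold, KISS1R at 57.1-fold, RGS16 at 48.4-fold, SIX3 at 47.4-fold and CALB2 at 31.7-fold, and SYT10 had a log2 ratio of 6.32 in place of 4.57. Toward NC-iSN2 the largest among genes with at least 50 CPM there were HOTAIRM1, a non-coding RNA of the HOXA cluster (1239-fold, 484 to 4550, from 4 UMIs in NC-iSN1, and 437-fold over all nuclei, 265 to 782), SCML4 (143-fold), STAC (105-fold), CSMD1 (63.1-fold), CRTAC1 (60.5-fold), FAM163A (55.6-fold) and BMPER (50.8-fold). HOTAIRM1 lies on chromosome 7 from 27095647 to 27100265 and is annotated as antisense. The counting is not stated to use strand, so its reads cannot be told from those of overlapping genes.

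Genes of peripheral sensory neurons were lower in NC-iSN1 as a list. Their median log2 ratio, NC-iSN1 over NC-iSN2, was -1.09, at percentile 0 of the random lists. Of 12 members with at least 20 CPM, 8 were higher in NC-iSN2, 1 was higher in NC-iSN1 and 3 stayed within 2-fold. The intermediate filament PRPH was 4.29-fold higher in NC-iSN2, the transcription factor ISL1 2.60-fold, DRGX 3.21-fold and the sodium channel SCN9A 2.36-fold. POU4F1 differed by a ratio of 1.24 (1.09 to 1.42), at 18.6 CPM in NC-iSN1. The touch and proprioceptor list had a median of -0.56 at percentile 0.12, with 6 of 11 members higher in NC-iSN2, including ASIC2 (8.43-fold), NTNG1 (8.11-fold) and SCN1A (6.49-fold), and with CALB2 higher in NC-iSN1. RUNX3 was below 1 CPM in both, and the neurofilament NEFH was at 9.90 and 6.84 CPM.

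Ion channel lists also lay toward NC-iSN2. The lists share members, so they are not independent of each other. PIEZO2 is in the peripheral sensory neuron, touch and mechanically gated lists, ASIC2 in the last 2 of these, and SCN9A and SCN1A are also sodium channel members. Mechanically gated and related channels had a median of -0.63 at percentile 1.22, with 4 of 6 members higher in NC-iSN2, among them the potassium channels KCNK10 (13.1-fold) and KCNK2 (8.96-fold). Voltage-gated sodium channels had a median of -0.58 at percentile 1.18. SCN10A was at 3.37 and 6.56 CPM. Calcium channels had a median of -0.58 at percentile 1.37, with CACNA2D3 8.87-fold and CACNA1B 2.58-fold higher in NC-iSN2. With random lists matched on gene length too, the mechanically gated list was at percentile 3.31, as it was at 3.95 over all nuclei, and the calcium channels at 10.0. The calcium channels were at 6.29 with members of at least 50 UMIs. With 5 CPM added they were at 9.42 and the touch and proprioceptor genes at 2.71. Potassium and HCN channels (percentile 3.96, and 1.29 with 5 CPM added) and TRP channels (14.6) lay inside the random lists, although KCNH1 was 25.9-fold higher in NC-iSN2. TRPV1 was at 4.24 and 4.71 CPM and TRPA1 at 4.83 and 1.77 CPM. Neurotrophic factor receptors lay at percentile 3.35, and at 2.25 with members of at least 50 UMIs. The nociceptor and peptidergic list lay at 64.3, with members on both sides. The purine receptor P2RX3 was 12.4-fold higher in NC-iSN2 and the nicotinic receptor CHRNA3 14.8-fold higher in NC-iSN1, which was 23.0-fold without nuclei whose barcodes occur in both tables.

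Transcription factors were divided. The sensory neuron transcription factors had a median of 0.43 at percentile 98.7, with INSM1 23.3-fold, EYA2 5.94-fold (3.34-fold over all nuclei) and ONECUT2 3.66-fold higher in NC-iSN1 and 2 members, DRGX among them, higher in NC-iSN2. INSM1 was 46.0-fold without nuclei whose barcodes occur in both tables. This list was at percentile 90.3 with random lists matched on length. The subtype factors lay at percentile 9.66, and at 1.61 over all nuclei. Among them BCL11B (9.36-fold) was higher in NC-iSN1 and SHOX2 (73.1-fold, 42.5 to 138.0) and ETV5 (2.31-fold) in NC-iSN2. Without nuclei whose barcodes occur in both tables BCL11B was 14.1-fold higher. NEUROG2 was at 3.77 CPM in NC-iSN1 and 0.121 CPM in NC-iSN2, a ratio of 31.3 (10.5 to 154), of 87.1 without those nuclei and of 19.2 over all nuclei.

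The retinoic acid response list was split, at a median of -0.47 and percentile 3.15, and at percentile 2.01 with random lists matched on length and 2.14 with median of ratios scaling. Of 8 members with at least 20 CPM, 5 were higher in NC-iSN1, against the sign of the median, and 3 in NC-iSN2. MEIS2 was 32.2-fold and the receptor gene RARB 7.73-fold higher in NC-iSN2, the culture given retinoic acid. The binding proteins CRABP1 (19.3-fold) and CRABP2 (11.3-fold) were higher in NC-iSN1, and CRABP1 was 29.2-fold higher without nuclei whose barcodes occur in both tables. HOX genes of groups 1 to 4 had a median of -2.62 over 5 measured members, at percentile 0, and gave no value with members of at least 50 UMIs, which left fewer than 5. Over all nuclei HOXB3 had 0 UMIs in NC-iSN1 and 20.8 CPM in NC-iSN2. The ratio was 308 with NC-iSN1 set to the floor of 3 counts over the library, and its exact interval starts at 250.2.

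Neuronal cytoskeleton and growth genes were higher in NC-iSN1, with a median of 0.88 at percentile 98.7. Of 25 members 13 were higher in NC-iSN1 and 1 in NC-iSN2. STMN1 was 6.26-fold, TUBB2A 5.13-fold and TUBA1A 4.60-fold higher. Immediate early and stress genes had a median of 1.27 at percentile 100, with JUND 6.76-fold and IER2 3.81-fold higher. Notch pathway and proneural genes (percentile 99.7), the mesenchymal markers (99.5) and the extracellular matrix (97.9) also lay above the random lists. Short genes as a whole were higher in NC-iSN1, with a Spearman rank correlation of ratio and gene length of -0.455 across genes, which are not independent replicates. TUBB2A, TUBA1A, JUND and IER2 are among the genes shorter than 19919.5 bp, whose median log2 ratio was 1.01 in neuron-like nuclei. Ribosomal protein genes took 2.68% of UMIs in neuron-like nuclei of NC-iSN1 and 1.07% in those of NC-iSN2. Matched on length, the cytoskeleton list was at percentile 93.4 and the Notch list at 95.2. Mesenchymal and extracellular matrix genes were at 96.6 and 88.8 over all nuclei, and the extracellular matrix was at 97.3 with members of at least 50 UMIs. Free RNA was not removed, so their places in neuron-like nuclei do not show that neurons make these messages.

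The remaining lists lay inside the random lists as first computed, and 3 of them lay above in an alternative. With 5 CPM added the neural crest or glial list was at 98.1, and with members of at least 50 UMIs the central nervous system neuron list was at 99.0 and the neuroepithelial progenitor list at 97.7. The remaining lists were axon guidance (percentile 36.7), where PLXNA4 was 18.6-fold higher in NC-iSN2 and SLIT2 13.3-fold higher in NC-iSN1 (24.0-fold without nuclei whose barcodes occur in both tables), synaptic vesicle genes (50.9), general neuronal markers (67.1), other transmitter identities (33.9), neural crest or glial (95.7), neuroepithelial (96.1), central neuron (91.0), cycling (92.2), pluripotent (49.5), epithelial (52.5), melanocyte (26.2) and endothelial markers (17.9). For the nociceptor, other transmitter and epithelial lists the mean had the opposite sign of the median.

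**Figure D2:**
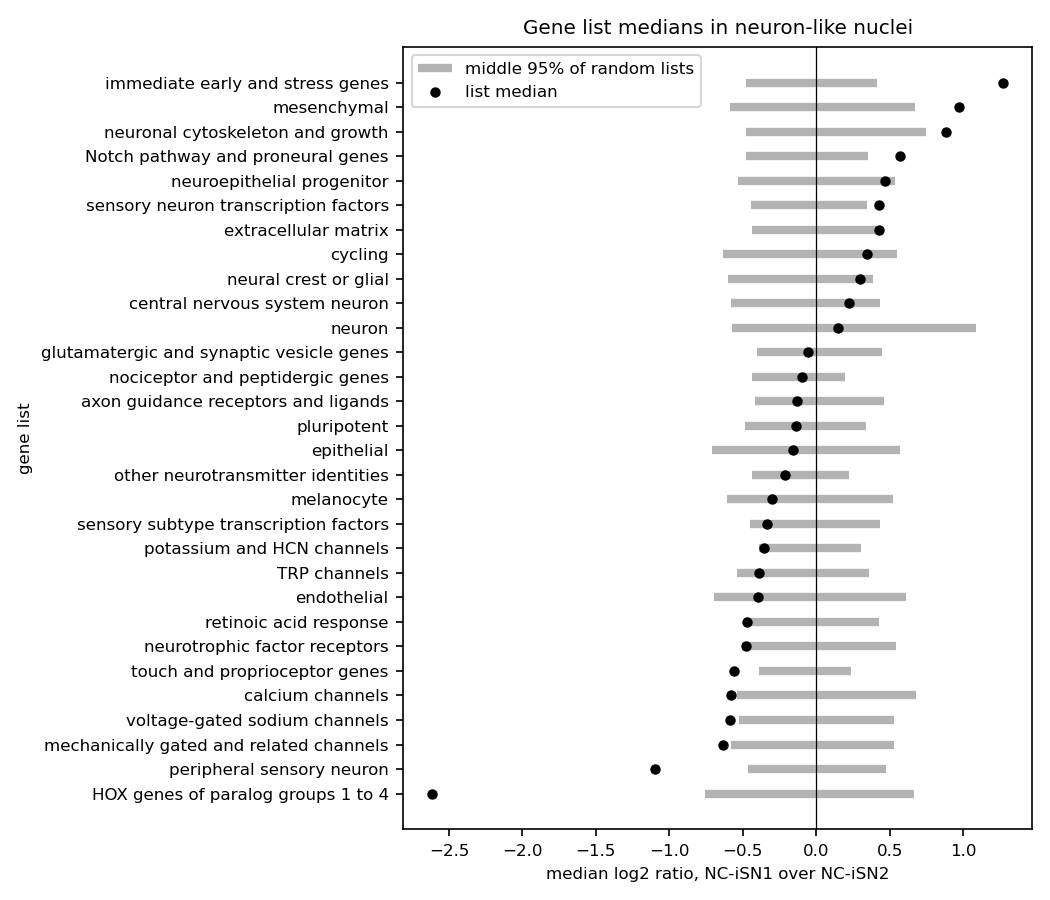
Median log2 ratio, NC-iSN1 over NC-iSN2, of 30 gene lists in neuron-like nuclei (points), with the middle 95% of 10000 random lists matched on expression (grey bars). The peripheral sensory neuron list is at -1.09 and the immediate early and stress list at 1.27.

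Shares of nuclei with a receptor UMI were read beside those of non-neuronal classes, because neuronal messages were found in every class. STMN2 was at 1799 CPM in neuron-like and 1640 CPM in mesenchymal-like nuclei of NC-iSN1. After thinning to 1000 UMIs, PIEZO2 was seen in 44.5% of NC-iSN2 neuron-like nuclei (43.6 to 45.5), 44.4% of mesenchymal-like (42.3 to 46.5) and 32.4% of glial-like nuclei (27.9 to 37.1). In NC-iSN1 it was seen in 13.7% (13.1 to 14.2), 21.0% (19.6 to 22.6) and 10.9%. The neuron-like share of PIEZO2 was thus above the glial-like share and not above the mesenchymal-like share in either library. In the joint clustering, 1102 of the 2234 mesenchymal-like nuclei of NC-iSN2 fell in a cluster named neuron-like, so that reference class is uncertain. TRPM8 was seen in 7.71% of NC-iSN1 neuron-like nuclei (7.31 to 8.13), 5.41% of mesenchymal-like and 7.08% of glial-like nuclei (5.58 to 8.83), so the neuron-like share did not stand above the glial-like background. In NC-iSN2 the TRPM8 share was 0.592% in neuron-like nuclei, and 0.373% without nuclei whose barcodes occur in both tables. It was 0.671% in mesenchymal-like nuclei and 0 of 420 glial-like nuclei, where the exact upper limit was 0.874%. These 2 background values include nuclei whose barcodes occur in both tables, so they are not set against the 0.373%. Such nuclei made up 6.29% of neuron-like, 7.48% of mesenchymal-like and 7.86% of glial-like nuclei of NC-iSN2. RET in NC-iSN2 was seen in 14.6% of neuron-like nuclei against 8.59% and 7.62%. Without thinning, PIEZO2 was seen in 23.8% and TRPM8 in 14.2% of neuron-like nuclei of NC-iSN1, and in 67.3% and 1.33% of those of NC-iSN2. Median depth in NC-iSN1 was 1692 UMIs in neuron-like, 1890 in mesenchymal-like and 1863 in glial-like nuclei, and in NC-iSN2 it was 2073, 2208 and 1946.

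**Figure D3:**
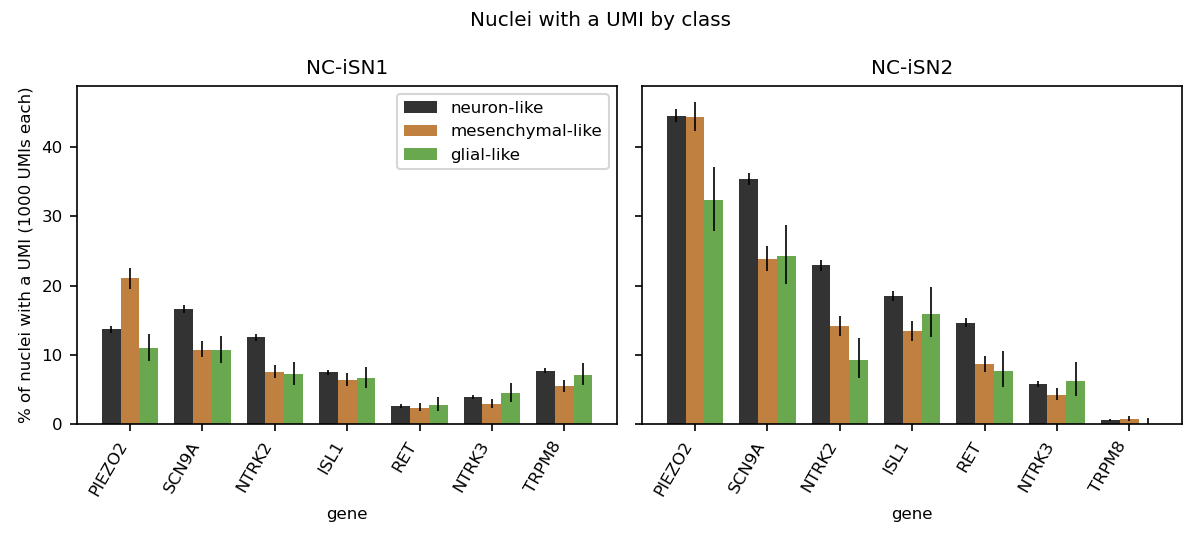
Percent of nuclei with at least 1 UMI of each gene after thinning to 1000 UMIs, by class and library, with exact 95% intervals as error bars. In NC-iSN2 PIEZO2 is at 44.5% of neuron-like and 44.4% of mesenchymal-like nuclei.

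The receptor pairs below were seen together in a nucleus at close to the product of their shares. PIEZO2 with TRPM8 was seen in 1.13% of NC-iSN1 neuron-like nuclei (0.976 to 1.30), beside a product of 1.05%, and in 0.233% of NC-iSN2 nuclei (0.152 to 0.342), beside 0.264%. PIEZO2 with NTRK2 was seen in 10.9% of NC-iSN2 nuclei (10.3 to 11.4), just above the product of 10.2%. Free RNA was not removed, so these joint shares do not show which receptors a cell makes.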

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

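The contrast of neuron-like with mesenchymal-like nuclei went in opposite directions in the 2 libraries for the preset gene PIEZO2, and the difference itself was not tested. The log2 ratio was -0.65 (-0.73 to -0.56) in NC-iSN1, at 156 CPM in neuron-like and 244 CPM in mesenchymal-like nuclei. In NC-iSN2 it was only 0.0804 (0.0277 to 0.133), at 679 and 642 CPM. In the joint clustering, 1102 of the 2234 mesenchymal-like nuclei of NC-iSN2 fell in a cluster named neuron-like, so the name of that class is not settled.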

How the results depend on the processing

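The alternatives chosen after the results were seen are those marked as added. No value called above the minimum changed sign in the alternatives run. No paired analysis was possible because each group has 1 library, and no replicate could be left out. The filters on nuclei removed at most 1 nucleus per library and Scrublet marked 0, so those alternatives say nothing about stability. At a minimum of 50 CPM the numbers of genes were lower by construction, with 666 genes over all nuclei and 658 in neuron-like nuclei higher in NC-iSN2. With no minimum and 1 CPM added, which changes both choices, these were 2070 and 2048, and 2935 were higher in NC-iSN1 in neuron-like nuclei, with the cause not tested. Of the 6 lists above and 6 below the random lists, 6 and 4 stayed with 5 CPM added, 5 and 4 with at least 50 UMIs, 4 and 5 over all nuclei, 6 and 6 with median of ratios (8 below in all), and 3 and 4 with length matching, added after seeing the data. Neuron-like shares of NC-iSN1 and NC-iSN2 were 75.9% and 82.3% at resolution 0.5, 74.7% and 89.9% with joint clustering, and 82.9% and 82.3% with unnamed clusters included (added after seeing the data). In the joint clustering, 1102 of 1136 nuclei of a neuron-like cluster of NC-iSN2 were mesenchymal-like when that library was clustered by itself, a count added after seeing the data. The unnamed NC-iSN2 nuclei entered these shares as well. At resolution 0.5 every NC-iSN2 cluster was named. In the joint clustering, 852 of the 1202 unnamed NC-iSN2 nuclei fell in a neuron-like cluster and 248 in another, counts also added after seeing the data. The cause of the remaining moves was not tested. Shares of nuclei were higher at greater depth. In NC-iSN1 and NC-iSN2, thinned to 2000 UMIs, PIEZO2 was seen in 27.2% and 68.9% of neuron-like nuclei, TRPM8 in 14.5% and 1.02%, both in 3.67% and 0.510%, and cycling genes in 5.04% and 3.17% of all nuclei. Not thinned these were 23.8% and 67.3%, 14.2% and 1.33%, 3.73% and 0.771%, and 4.75% and 3.79%. Without nuclei whose barcodes occur in both tables, added after seeing the data, NC-iSN2 had PIEZO2 in 45.5% and TRPM8 in 0.373% of neuron-like nuclei.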

Other observations

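Of the tests in this part, those of barcode overlap and of the unshared nuclei in the NC-iSN2 cluster, of mitochondrial and ribosomal RNA, and of length-matched lists were chosen after the results were seen.

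Values of 2 retinoid genes, chosen after they were seen, are given for non-neuronal nuclei, where the retinoic acid list was not tested. In mesenchymal-like nuclei RARB stood at 91.6 CPM in NC-iSN1 and 485 CPM in NC-iSN2, and DHRS3, a retinaldehyde reductase, at 80.5 and 328 CPM. In glial-like nuclei DHRS3 stood at 38.8 and 302 CPM.

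An NC-iSN2 cluster of 641 neuron-like nuclei was led by genes high in NC-iSN1, such as SYT10, KCTD8 and NUP62CL. Of its barcodes 85.0% also occur in the NC-iSN1 table. That share was 1.48% in the other neuron-like NC-iSN2 nuclei and from 4.33% to 8.88% in the mesenchymal-like and glial-like clusters of NC-iSN2. The 85.0% argues against an NC-iSN1-like cell state as the source of the whole cluster. Each of the 545 shared barcodes matched its own NC-iSN1 partner best, at a median percentile of 100, while partners shifted along the list lay at 52.6. The comparison set meant as a control did not stay low. Among the other 376 shared barcodes 99.5% also matched their own partner best, and they shared a mean of 5.91 rare genes with it against 0.109 with a shifted partner, so a mix of both libraries under shared barcodes is a candidate source that reaches beyond this cluster. The 96 nuclei with unshared barcodes held the leading genes at 0.395 of the level of the shared ones, and an NC-iSN1-like state cannot be told apart there from NC-iSN1 barcodes below the tables' minimum.

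Short genes were higher in NC-iSN1 and long genes higher in NC-iSN2. Within glial-like nuclei the rank correlation was 0.883 of that over all nuclei, too high for a mix of cell classes by the preset limit. That test cannot decide, because free RNA was not removed and neuronal messages were found in every class, the glial-like nuclei included. A mitochondrial share of UMIs 0.860 of that of NC-iSN2 went against the prediction for whole cytoplasm, mitochondria included. That ratio was 1.04 in the unnamed clusters. It cannot decide on cytoplasmic RNA that came without mitochondria. Ribosomal protein RNA was 2.168 to 3.05 times higher in NC-iSN1 across classes. The nuclear RNA MALAT1 took 8.57% of UMIs in NC-iSN1 and 11.8% in NC-iSN2. Free or cytoplasmic RNA without mitochondria and a difference between the cultures cannot be told apart without replicate preparations. Matched on length, the peripheral sensory neuron list stayed at percentile 0 and the stress list at 98.7, while the cytoskeleton list moved to 93.4. The cytoskeleton median of 0.88 did not move. The middle 95% of random lists went from -0.48 to 0.75 before and to -0.15 to 1.03 after, so gene length may account for the place of that list. The same step also used coarser expression bins and left out genes without a length, and these changes were not separated from length.

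An NC-iSN1 cluster of 2202 neuron-like nuclei was led by genes high in NC-iSN2, including BMPER and PLXNA4. The hypothesis of an NC-iSN2-like minority was left undecided. Over 1078 genes higher in NC-iSN2, the median log2 ratio to the other neuron-like nuclei was 0.26 (quartiles 0.06 and 0.56). By the limits set beforehand this was too small to call and too large to exclude, and HOTAIRM1 had 0 CPM in the cluster. A positive shift was not particular to it. Another neuron-like NC-iSN1 cluster, of 4220 nuclei, had a median of 0.15, and the remaining ones lay from -0.31 to 0.0061. Genes higher in NC-iSN1 had a median of -0.29 in the cluster of 4220 nuclei and -0.087 in that of 2202. In the cluster of 2202 nuclei, 3.63% of barcodes were found in the NC-iSN2 table, 0.877 of the share of the other neuron-like nuclei. The cluster of 4220 nuclei raised that reference, at 7.42%, and the remaining ones lay lower, from 2.35% to 3.17%. A share of 3.63% argues against NC-iSN2 reads under shared barcodes as the source of the whole cluster. NC-iSN2 barcodes below the tables' minimum could not be checked.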
